A study of Mus musculus with 5 samples.

How the data were processed

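Single-cell RNA of CD45+ liver cells from untreated and aCD40-treated mice, and of EYFP+ liver and tumor cells from treated mice, was measured with inDrops in 26 libraries of 5 pools, per the labels' protocols. Mice carried an IL-12p40 reporter and MC38 flank tumors grown for 7 days, received 5 mg/kg of aCD40 or nothing, and were taken 2 days later. Dead cells were excluded by 7AAD at the sort. Pools 1 to 4 held 16 libraries of CD45+ liver cells, 2 untreated and 2 treated per pool, and pool 5 held 10 libraries of EYFP+ cells with the letters I, J and K in each tissue. The series text gives 2 untreated and 2 treated mice, 2 EYFP+ livers and 3 EYFP+ tumors. Treated CD45+ libraries are named by a code that the labels of pool 5 pair with aCD40, so the treatment was deduced from there.

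The deposited tables hold raw counts (UMIs) per cell and gene, made by the authors with bcl2fastq and STAR on GRCm38, per the submitters' processing notes, which give no versions. Filters on barcodes are not stated. From the values, every entry was a whole number, the smallest cell held 120 UMIs, no cell reached 15% mitochondrial counts and each library had its own lowest total. The tables hold 26223 cells, 22631 genes (13 mitochondrial) and 23792307 UMIs. Reads were not used here.

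Cells with at least 300 UMIs and 150 genes and at most 20% mitochondrial UMIs were kept, which removed 1958 cells and left 24265. Scrublet, in scanpy 1.11.5, was run per library with an expected doublet rate of 0.05, and its 204 calls (0.841% of these cells) were removed. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were used, without mitochondrial, ribosomal protein, immunoglobulin and T cell receptor variable genes. Clusters came from 30 principal components, 15 neighbours, a Jaccard-weighted graph and Leiden clustering at a resolution of 1.5 with seed 0 (python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0). CD45+ and EYFP+ cells were clustered apart, with no batch integration. Figures were drawn with matplotlib 3.10.9.

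Clusters were named from 19 marker lists. Among genes found in at least 10% of a cluster's cells, the 30 of highest fold over the median CD45+ cluster (pseudocount 20 CPM) were compared with the lists. A class was given when it had the most markers, at least 3 of them in those 30, and no other class had more among the top 10. A name could also come from at least 3 markers among the top 10 within the EYFP+ sort or within the parent cluster, and the subsets of dendritic cells shared 1 class. Clusters with at least 5 markers of another class were divided with 1000 variable genes, 15 components and a resolution of 0.5. Other clusters stayed unnamed. The marker lists were fixed with the design, and the details of dividing and naming were set after the data had been seen. Names end in -like because they rest on transcripts alone.

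The design, the gene lists, the rule for naming genes and most other settings were fixed before the data were examined. Counts of each class were summed per pool and treatment, 4 sums per group, and for EYFP+ cells per letter and tissue with runs of a letter added together, 3 sums per group. Sums of fewer than 20 cells were left out. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood fit), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Class shares were tested with edgeR on cell counts per class without TMM, beside an exact two-sided permutation test. In all, 24 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where at least 5 members were measured. A fold against a group with no counts was computed against a floor of 3 counts over the group and is a lower bound, and with 1 to 3 counts a ratio is given with its 95% counting interval. The difference of a change between classes was tested with a class by treatment term. Il12b was also counted in cells thinned to 500 UMIs, shallower cells being left out, with Clopper-Pearson intervals. Gene levels in CPM use TMM factors, except for eYFP, Il12b and the comparisons of levels between classes or groups of cells in the closing section. Values said to be without TMM factors are a further exception. Gene coordinates are from the GENCODE annotation of GRCm38.

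Named genes were, per test, those past the threshold with at least 30 CPM in the higher group and no overlap between groups: the 10 of largest rise and the 6 of largest fall, without predicted genes and antigen receptor variable segments. The 4 members of largest change in each called list were added, as were genes fixed with the design, such as Il12b, Tnf, Ifng and Cd40. The text names part of these, and some of the fixed genes are not reported here and are left out of the counts over settings. The eYFP transcript, the myeloid genes Lyz2 and S100a8 in lymphoid classes, and genes of the closing section outside the rule were chosen after their values were seen, as was the test of pDC-like cells.

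Depth limits single genes. Median depth per library ran from 435.5 to 1326.5 UMIs in the cells kept, so a gene at 100 CPM gives about 1 UMI in every 10 cells of 1000 UMIs, and statements rest on sums. Pool numbers were checked as a pairing: residuals of same-numbered untreated and treated sums correlated with r of 0.267, 0.324, 0.331 and 0.286 across 2415 genes, which are not independent replicates. Such correlations were as high between the pools of one set (pools 1 and 2, pools 3 and 4). The labels do not state a pairing, so none was used in the main tests, and the pool was tried as a block.

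Alternatives were the DESeq2 1.42.0 Wald test, RLE factors, no low-count filter, each library as its own unit, the pool or letter as a block, leaving out each pool or letter, doublet calls kept, cells of at least 600 UMIs, a resolution of 0.8, and 50 random draws of 2 units of 4 libraries per group. For shares TMM factors were tried as well, for the lists an estimated correlation, and for Il12b thinning to 300 UMIs. Added after the data had been seen were no cell filter beyond deposition, clusters made without 4015 changed genes, sums and tests by the sets of pools 1 and 2 and pools 3 and 4, the set as a term, and Kupffer-like cells with at least 3 marker UMIs.

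The fits were tested on simulated data with the depths of the real sums. The simulated sums were independent, with the common dispersion of each comparison, and held no difference between the sets of pools. The rates that follow therefore do not describe data with such sets. Of genes changed 4-fold, 93.3 to 100% were recovered, and of those changed 2-fold 33.3 to 84.0%, while 0.0554 to 1.44% of unchanged genes were called. The changed list was called in each of the 9 comparisons, and 1 other list was called in 2 of them. For shares, 2 of 2 classes moved at least 2-fold were called, with a largest error of 0.760 on the log2 scale. The planned test of EYFP+ monocyte or macrophage-like cells was left out, since no such class had enough cells in both tissues. Libraries were not assigned to mice, and EYFP+ and CD45+ cells, which came from different pools, were set side by side only as values.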

Results

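Transcripts were counted in single cells of mouse liver and tumor with inDrops, a droplet method that tags each RNA molecule with a unique molecular identifier (UMI). The mice carried a reporter in which yellow fluorescent protein (EYFP) is made from the Il12b transcript, which encodes IL-12p40, and bore MC38 colon carcinoma tumors in the flank. They received 5 mg/kg of an agonistic antibody against CD40 (aCD40), a costimulatory receptor of antigen-presenting cells, or nothing, and cells were taken 2 days later. The series title names the purpose, the part of Kupffer cells and neutrophils in the liver toxicity of such treatment. CD45+ leukocytes of the liver came from 4 pools, each with 2 untreated and 2 treated libraries. EYFP+ cells of treated mice came from a further pool, with libraries of 3 letters each for liver and for tumor.

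After filtering, 24061 cells were kept, of which 17568 were CD45+ liver cells (5283 untreated, 12285 treated) and 6493 were EYFP+ cells (4844 from liver, 1649 from tumor). Summed per pool, the untreated CD45+ cells held 868165 to 1078693 UMIs and the treated cells 1691946 to 5207805. Median depth was 621 UMIs per untreated cell and 990 per treated cell, and 796 per EYFP+ liver cell and 589 per EYFP+ tumor cell. Pools 1 and 2 were shallower than pools 3 and 4 in both groups, with medians of 516 against 836 UMIs in untreated cells and 753.5 against 1181 in treated cells. The median share of mitochondrial UMIs per cell, averaged over pools, was 3.96% in untreated and 2.01% in treated CD45+ cells. The series text counts 2 untreated and 2 treated mice, and no label ties a library to a mouse, so every p-value describes pools and is too small for a statement about mice. Adjusted p-values of genes and class shares are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, levels are counts scaled to the same total with TMM factors (CPM) and given as mean ± SD over pools, and intervals and floors cover counting error only.

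Neutrophil-like cells became the largest class of the CD45+ liver cells after aCD40, rising from 6.02 ± 0.824% to 53.6 ± 3.18% of cells (SD, n = 4 pools per group). Kupffer-like cells, the resident macrophages of the liver, fell from 20.8 ± 2.80% to 1.19 ± 0.112%, and B-like cells fell from 33.4 ± 2.64% to 7.23 ± 0.339%. NK-like cells rose from 3.87 ± 1.17% to 8.03 ± 2.30%, while T-like cells fell from 16.5 ± 0.395% to 8.35 ± 0.563% and DC-like (dendritic) cells from 7.08 ± 1.61% to 1.71 ± 0.508%. Plasmacytoid pDC-like cells fell from 3.69 ± 0.915% to 1.04 ± 0.253%. On the log2 scale the changes were 3.15 ± 0.12 (SE) for neutrophil-like cells, -4.12 ± 0.14 for Kupffer-like cells, -2.20 ± 0.09 for B-like cells, 1.04 ± 0.27 for NK-like cells, -0.98 ± 0.08 for T-like cells and -2.03 ± 0.25 for DC-like cells. Adjusted p-values ran from 0.00934 for basophil or mast-like cells, at 0.194 ± 0.146% against 0.555 ± 0.139% (adjusted p = 0.0538 without pool 4 and 0.0863 within pools 1 and 2), to 2.55e-08 for Kupffer-like cells. For each of the 12 classes the exact two-sided permutation test of 4 against 4 pools gave 0.0286, the smallest value it can give.

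Monocyte-like cells made up 7.74 ± 1.47% of untreated and 12.9 ± 2.00% of treated cells, a log2 change of 0.73 ± 0.17. The inflammatory macrophage-like class rose from 0.0539 ± 0.0366% to 3.01 ± 2.90%, and in treated cells its share was 0.504% in pools 1 and 2 and 5.51% in pools 3 and 4. Genes that aCD40 changed also shaped the clusters, so shares were counted again in clusters made without the 4015 genes called in any class. There the log2 changes were 2.90 for neutrophil-like, -4.81 for Kupffer-like, -2.14 for B-like, 1.25 for NK-like, -0.70 for T-like and -1.22 for DC-like cells. Those of monocyte-like cells (0.28, adjusted p = 0.429) and inflammatory macrophage-like cells (0.28, adjusted p = 0.419) were no longer called. Other cell filters and resolutions also moved some classes. At a Leiden resolution of 0.8 the log2 changes were 3.25 for DC-like and -3.32 for monocyte-like cells, and in cells of at least 600 UMIs -0.41 for monocyte-like (adjusted p = 0.252) and -5.68 for inflammatory macrophage-like cells. Shares within one sort rise and fall against each other. With class counts scaled by TMM, T-like cells changed by -0.22 on the log2 scale (adjusted p = 0.180), and the ratio of neutrophil-like cells to B-like plus T-like cells went from 0.122 ± 0.0239 to 3.44 ± 0.170. Part of cluster 25, which mixed Kupffer cell and endothelial markers, went from 0.667 ± 0.0892% to 0.0915 ± 0.0310%, and the parts of clusters 20 and 15 left unnamed held no untreated cell and 2.29 ± 0.164% of treated cells.

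Libraries of pools 1 and 2 resembled one another, as did libraries of pools 3 and 4, more than libraries resembled each other across these 2 sets of pools, in both groups. A chi-square statistic of summed gene counts per degree of freedom, where 1 is counting error alone, had a median of 1.46 for pairs of treated libraries within either set and 7.90 for pairs across the sets, and of 1.24 and 2.31 for untreated libraries. No label names the sets, and whether they are the 2 mice per group is not known. Within pools 1 and 2, and then within pools 3 and 4, the log2 change of shares was 3.07 and 3.25 for neutrophil-like, -4.06 and -4.18 for Kupffer-like, -2.16 and -2.24 for B-like and 1.09 and 1.00 for NK-like cells. It was -0.88 and -1.09 for T-like, -2.72 and -1.43 for DC-like and 0.32 and 1.17 for monocyte-like cells. With each set summed, which leaves 2 units per group, 905 genes changed in Kupffer-like, 1322 in neutrophil-like, 753 in monocyte-like, 224 in NK-like, 293 in T-like, 2548 in B-like and 670 in DC-like cells. The effect of aCD40 differed between the sets, by an interaction term, for 8, 108, 142, 11, 100, 76 and 2 genes in that order.

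**Figure D1:**
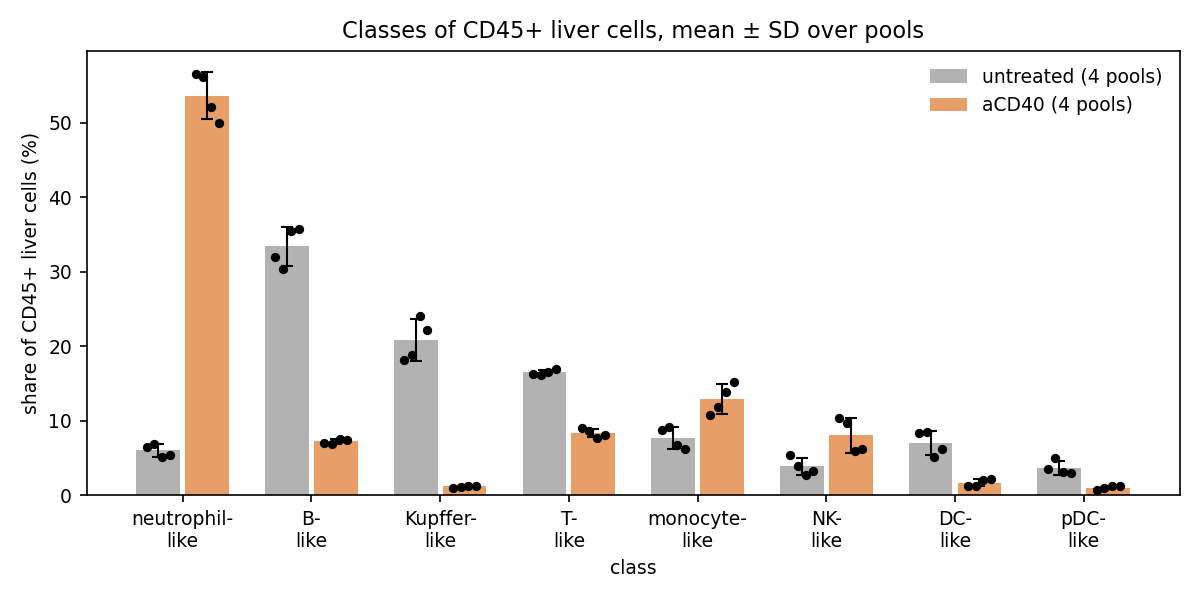
Share of CD45+ liver cells (percent, y axis) in 8 classes (x axis) in untreated and aCD40-treated pools; points are pools and bars the mean of 4 pools, with whiskers of 1 SD. Neutrophil-like cells rose from 6.02% to 53.6% and Kupffer-like cells fell from 20.8% to 1.19%.

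Kupffer-like cells after aCD40 had fewer transcripts of resident genes such as Clec4f and more of Cxcl9 and Cd40. Transcripts of Clec4f, a lectin of Kupffer cells, were 136-fold lower (7961 ± 189 to 54.8 ± 40.1 CPM, n = 4 pools, adjusted p = 1.11e-18), and Cd5l, a secreted scavenger protein, was 16.3-fold lower. The chemokine gene Cxcl9, an interferon-gamma target, was 106-fold higher (64.4 ± 42.1 to 6645 ± 697 CPM, adjusted p = 5.86e-20). Cd40, the receptor bound by the antibody, was 23.8-fold higher (50.8 ± 7.97 to 1215 ± 249 CPM, adjusted p = 2.48e-14). Of 1581 genes tested, 733 changed, 353 up and 380 down, in 1083 untreated and 149 treated cells.

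Among the genes that rose were Ubd, a ubiquitin-like modifier induced by cytokines, with no UMI in untreated cells and 242 in treated ones (at least 455-fold higher), H2-M2 (at least 135-fold), Ccl22 (at least 86.4-fold), the acute-phase gene Saa3 (at least 65.8-fold), Nudt17 (at least 58.2-fold) and Ly75 (at least 50.7-fold). The actin-bundling gene Fscn1, with 1 UMI in untreated cells, rose with a ratio of 1629 (290.0 to 64554), where the range is the 95% counting interval, Cd63 with 321 (86.9 to 2685) and the migration receptor Ccr7 with 299 (51.3 to 12018). Ccl5 was 159-fold higher. Cd163, a hemoglobin scavenger receptor, had 854 UMIs in untreated cells and none in treated ones (at least 50.5-fold lower), as did Mrc1 (at least 28.0-fold lower), Fabp7 (at least 15.8-fold), Cd207 (at least 13.7-fold), Pitpnc1 (at least 11.8-fold) and Adcy4 (at least 10.1-fold).

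Of 18 Kupffer cell identity genes measured, 15 fell, none rose and 3 were not called, with 15 also called when adjusted over the list alone (camera adjusted p = 4.67e-08, adjusted p = 0.0423 with an estimated correlation). They included Timd4, 5.39-fold lower, and Vsig4, with a treated to untreated ratio of 0.00557 (6.74e-04 to 0.0202). Many genes of this list, such as Clec4f, Timd4 and Vsig4, were also markers used to name clusters. The list test is thus not independent of the naming. Marco, a scavenger receptor, was not called (1497 ± 727 to 1699 ± 1372 CPM, adjusted p = 0.658), but was higher by 0.55 on the log2 scale in clusters made without the changed genes (adjusted p = 0.0108). Of 16 scavenging and iron handling genes 9 fell and 1 rose, 10 and 1 when adjusted over the list alone, among them Apoe (7.29-fold lower), C1qa (7.29-fold) and Timp2 (8.10-fold) (adjusted p = 0.00562, adjusted p = 0.0542 with an estimated correlation). Of 16 IFN-gamma response genes 11 rose and 1 fell, the same numbers adjusted over the list alone, among them Gbp2 (9.88-fold higher) and Cd274, which encodes PD-L1 (6.49-fold) (adjusted p = 2.93e-04, adjusted p = 0.0542 with an estimated correlation).

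Of 9 MHC class II genes 6 rose and none fell in Kupffer-like cells, 7 adjusted over the list alone, with H2-Ab1 3.11-fold and H2-Eb1 3.29-fold higher and the class II transactivator Ciita 4.19-fold (adjusted p = 0.0027, adjusted p = 0.172 with an estimated correlation). Of 14 MHC class I genes 9 rose, 9 adjusted over the list alone, including H2-K1 (2.33-fold) and Psmb9 (2.93-fold) (adjusted p = 0.00178, adjusted p = 0.132 with an estimated correlation). The IL-12 family and costimulation list had 4 of 5 genes up (adjusted p = 5.31e-04, adjusted p = 0.0423 with an estimated correlation), and the B cell activation list, with Cd40 and Cd83 (3.66-fold, but 0.67 on the log2 scale and adjusted p = 0.354 within pools 1 and 2), 6 of 7 (adjusted p = 4.93e-04, adjusted p = 0.0423 with an estimated correlation). Of 14 TNF and NF-kB genes 9 rose and 1 fell, 10 and 1 adjusted over the list alone, such as Bcl2a1b (13.4-fold) and Nfkb2 (10.3-fold) (adjusted p = 0.00103, adjusted p = 0.172 with an estimated correlation). Of 11 glycolysis genes 9 rose and 1 fell, such as Pgk1 (7.50-fold) and Pgam1 (5.46-fold) (adjusted p = 5.31e-04, adjusted p = 0.0542 with an estimated correlation). Dissociation stress genes, which follow tissue handling, had 8 of 15 lower and 1 higher, among them Jun (21.8-fold lower) (adjusted p = 0.0184, adjusted p = 0.172 with an estimated correlation). Il12b, Il12a and Ifng had no UMI in either group, and Tnf, with 33 and 15 UMIs, was too low to be tested over the 4 pools. Of the treated cells, 70 of 149 held at least 3 UMIs of both Kupffer cell and mature dendritic cell markers. Dendritic cells mixed into the class or caught in doublets stay open as a source of presentation genes. The same holds for Cd40, Ccr7, Ccl22, Fscn1 and Ly75 and for the costimulation, B cell activation and NF-kB lists. Clusters 15.1 and 15.2, the other named parts of the cluster that held these cells, were DC-like.

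The treated Kupffer-like cells were all in a part of cluster 15, and the untreated ones were 1082 cells of cluster 5 and 1 of that part. Of the treated cells, 100 of 149 held at least 3 UMIs of Kupffer cell markers (median 5), against 1082 of 1083 untreated cells (median 36). In clusters made without the changed genes, only pools 3 and 4 held enough treated cells (36 and 35), and there Clec4f fell by 6.78 on the log2 scale, while Cxcl9 rose by 6.94, Cd40 by 4.06 and H2-Ab1 by 0.75. The rises of H2-M2 (4.29), Cd63 (4.34), H2-Eb1 (0.77) and Ciita (1.37) were smaller there than over all cells of the class, and H2-DMb2 was not called (adjusted p = 0.0618). Tnf changed by 3.01 there (adjusted p = 4.45e-04) and by 0.93 in the cells with marker UMIs (adjusted p = 0.312). Of the 50 named genes called in Kupffer-like cells, 48 could be tested there and 44 were called in the same direction, and in the cells with marker UMIs 48 of 50 were.

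**Figure D2:**
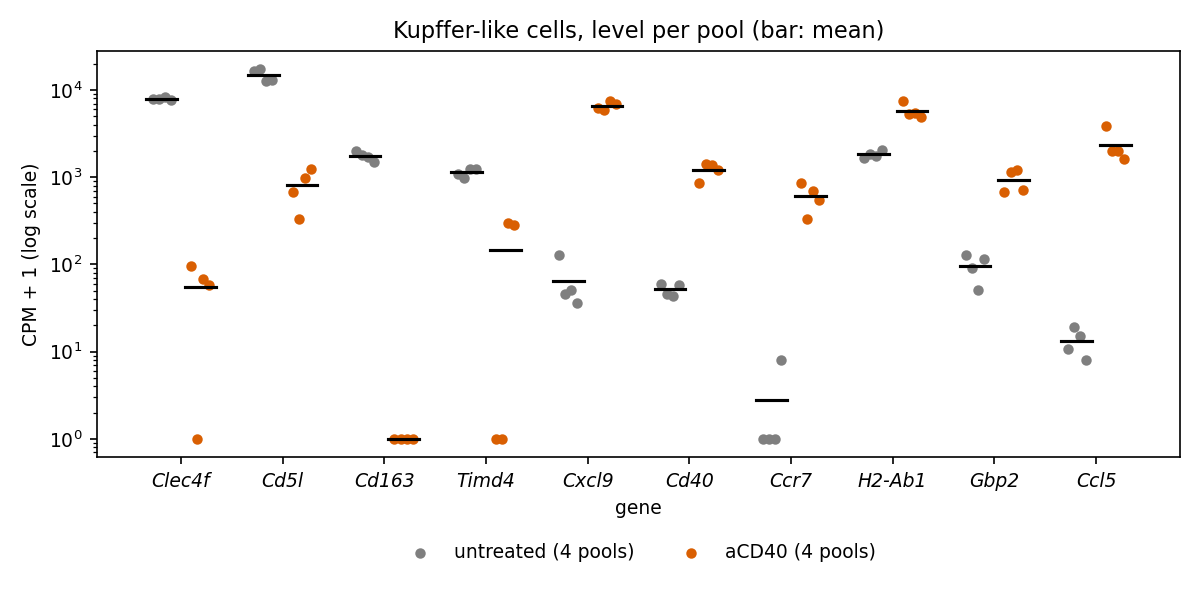
Level of 10 genes (x axis) in Kupffer-like cells in CPM plus 1 (y axis, log scale) for 4 untreated and 4 aCD40-treated pools; points are pools and bars mark means. Clec4f, Cd5l, Cd163 and Timd4 were lower and Cxcl9, Cd40, Ccr7, H2-Ab1, Gbp2 and Ccl5 higher in every treated pool than in every untreated pool.

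Neutrophil-like cells after aCD40 had more Tnf and Cxcl10 transcripts and fewer of Cxcr2. Tnf was 11.2-fold higher (310.1 ± 118 to 3521 ± 673 CPM, n = 4 pools, adjusted p = 7.06e-09), and the chemokine gene Cxcl10 was 26.9-fold higher (123 ± 139.9 to 3355 ± 998 CPM, adjusted p = 9.55e-06). Icam1, an adhesion molecule, was 19.1-fold higher and Cd274 11.4-fold. The chemokine receptor gene Cxcr2 was 2.17-fold lower (2763 ± 304 to 1273 ± 142 CPM, adjusted p = 1.41e-05), and Il1b was 1.47-fold lower from a high level of 22629.5 CPM, although not within pools 3 and 4 (-0.12 on the log2 scale, adjusted p = 0.180). Of 3804 genes tested, 1445 changed, 826 up and 619 down, in 323 untreated and 6481 treated cells.

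S100a9 rose slightly (1.29-fold, adjusted p = 0.0414) and was not called when any 1 pool was left out (adjusted p of 0.0650 to 0.0950). S100a8 was not called over the 4 pools (0.31 ± 0.17 on the log2 scale, adjusted p = 0.149). It was called within pools 1 and 2 (0.48, adjusted p = 1.04e-05), within pools 3 and 4 (0.44, adjusted p = 2.76e-05) and in clusters made without the changed genes (0.47, adjusted p = 0.0289). Genes with no UMI in untreated cells also rose, among them the interferon-induced Ifit2 (at least 58.6-fold higher), Gbp4 (at least 30.1-fold, adjusted p = 0.0629 without pool 4), Gbp3 (at least 20.3-fold), Mreg (at least 16.7-fold), the lipid-degrading Smpdl3b (at least 15.1-fold), Batf2 (at least 11.7-fold), Ifi206 (at least 9.48-fold), the lectin-like receptor gene Olr1 (at least 9.19-fold), Abcc1 (at least 9.05-fold) and Phf11b (at least 8.48-fold). Amz1 (84.9-fold), Ctc1 (61.6-fold), Csad (26.8-fold), Chac1 (26.3-fold), Fbxo31 (26.0-fold) and Camk1d (17.2-fold) were lower. Cd40 itself had 1 UMI in untreated and 259 in treated cells, a ratio of 12.8 (2.27 to 506) (adjusted p = 0.119 within pools 1 and 2).

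Of 21 type I interferon genes measured in neutrophil-like cells 21 rose, such as Ifit3 (26.5-fold) (adjusted p = 9.67e-11, adjusted p = 0.11 with an estimated correlation), and of 21 IFN-gamma response genes 20 rose, such as Gbp5 (52.4-fold) and Cxcl9 (15.3-fold) (adjusted p = 9.67e-11, adjusted p = 0.11 with an estimated correlation). Of 17 MHC class I genes 17 rose, with H2-Q7 18.1-fold higher (adjusted p = 2.39e-08, adjusted p = 0.11 with an estimated correlation). H2-Q7 and H2-Q6 are near-identical copies, so their split is uncertain here and in the other classes. Of 20 TNF and NF-kB genes 17 rose and 1 fell, 18 and 1 adjusted over the list alone, among them Sod2 (17.9-fold), Il1a (17.5-fold) and Traf1 (11.3-fold) (adjusted p = 2.09e-06, adjusted p = 0.11 with an estimated correlation). Of 9 chemokine genes 7 rose and 1 fell, including Ccl3 (8.88-fold) and Ccl5 (ratio 132 (36.6 to 1094)) (adjusted p = 0.00522, adjusted p = 0.236 with an estimated correlation). For the lists of this paragraph other than TNF and NF-kB, the counts were the same when adjusted over the list alone.

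Of 23 neutrophil activation genes 14 rose and 5 fell, such as the oxidase subunit Cybb (15.7-fold) and Nos2, which makes nitric oxide (ratio 39.6 (7.08 to 1565)) (adjusted p = 0.0107, adjusted p = 0.236 with an estimated correlation). Granule genes, made early in neutrophil maturation, had 9 of 12 up and 1 down, with Ngp 14.4-fold and Camp 11.8-fold higher (adjusted p = 0.00764, adjusted p = 0.11 with an estimated correlation). Ngp and Camp led cluster 12, which held 484 treated and 2 untreated cells, and Ngp was also a top gene of cluster 4. The granule gene Lcn2 was a top gene of clusters 0, 1, 3, 4 and 12. Whether Ngp and Camp rose outside cluster 12 was not tested. Of 15 glycolysis genes 11 rose, such as Tpi1 (5.67-fold) and Pgk1 (4.21-fold) (adjusted p = 0.00522, adjusted p = 0.115 with an estimated correlation). The IL-12 family list had 5 of 8 genes up (adjusted p = 0.0271, adjusted p = 0.237 with an estimated correlation), with Il12a at 2 and 443 UMIs, while Il12b had none. The B cell activation list had 5 of 8 up (adjusted p = 0.0398, 0.0521 with the pool as a block, adjusted p = 0.236 with an estimated correlation). Dissociation stress genes had 9 of 16 down and 2 up, such as Fosb (15.9-fold lower) and Atf3 (3.74-fold lower) (adjusted p = 0.00695, adjusted p = 0.237 with an estimated correlation). Untreated neutrophil-like cells lay mostly in cluster 19 (300 of 323) and treated ones in clusters 0, 1, 3, 4 and 12. In clusters made without the changed genes, 1527 genes changed.

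**Figure D3:**
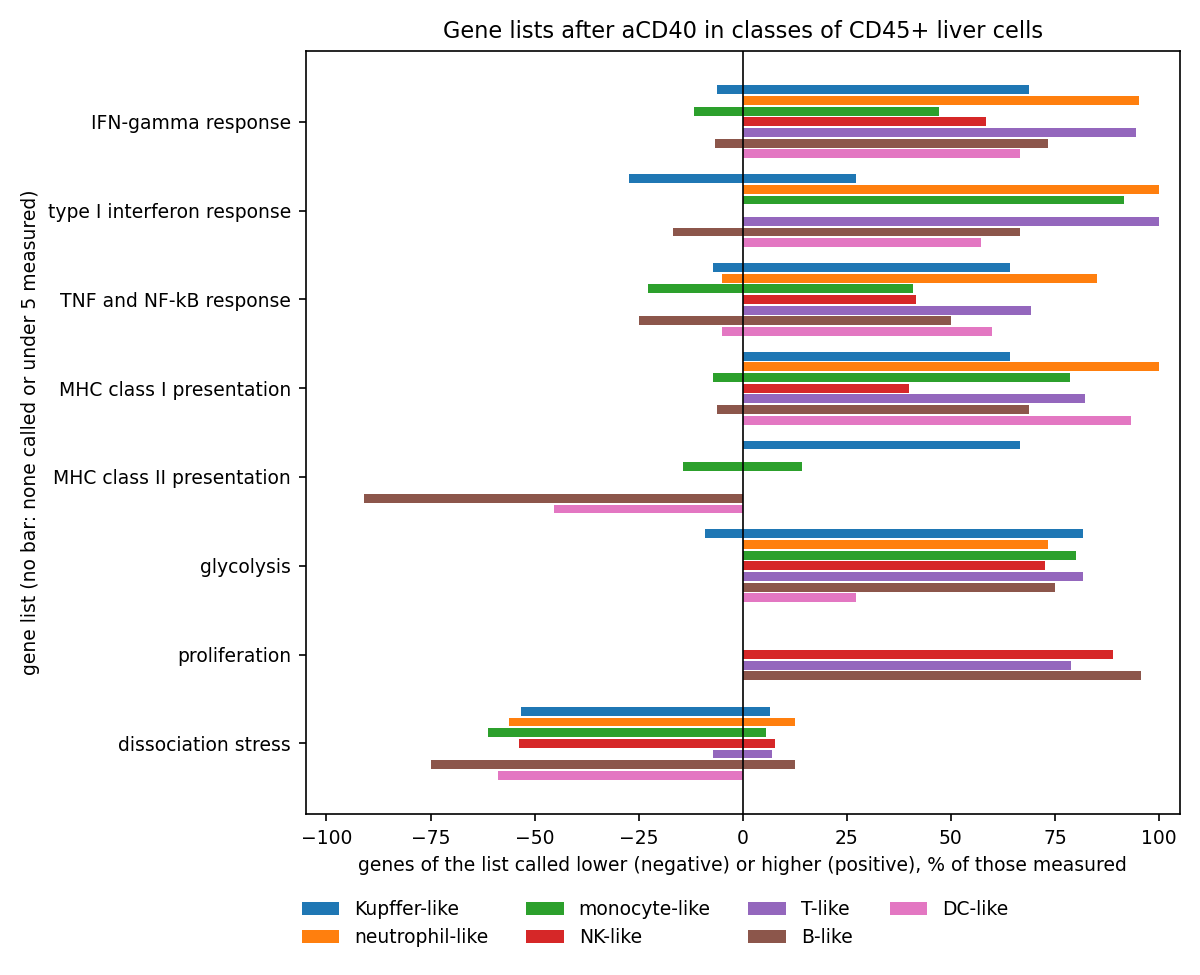
Percent of measured genes (x axis) of 8 gene lists (y axis) that rose (to the right) or fell (to the left, negative) after aCD40 in each of 7 classes of CD45+ liver cells, from tests on 4 untreated and 4 treated pools. In neutrophil-like cells 21 of 21 type I interferon genes rose, 6 of 9 MHC class II genes rose in Kupffer-like cells and 10 of 11 fell in B-like cells. With an estimated correlation these lists had adjusted p of 0.11, 0.172 and 0.0505 and were not called.

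Monocyte-like cells after aCD40 gained S100a8, S100a9 and Saa3 transcripts and lost Apoe. S100a9 had 2 UMIs in untreated cells and rose with a ratio of 382 (106 to 3152), S100a8 with 294 (101 to 1427), and the acute-phase gene Saa3 was 69.8-fold higher (28.7 ± 38.9 to 2011 ± 706 CPM, n = 4 pools, adjusted p = 9.51e-07). Apoe was 72.5-fold lower (2909.7 ± 208 to 42.9 ± 11.5 CPM, adjusted p = 2.41e-10). S100a8 and S100a9 are also markers of neutrophils, in which S100a8 stood at 28829 CPM after treatment against 2173 CPM here, without TMM factors. In treated monocyte-like cells 4 neutrophil markers stood at 1.99% (Retnlg) to 12.7% (Acod1) of their level in neutrophil-like cells. Free RNA and doublets were not tested in this class. Neutrophils thus stay open as a source of part of S100a8, S100a9, Lcn2, Wfdc21 and Acod1 here. Of 2654 genes tested, 1061 changed, 549 up and 512 down, in 417 untreated and 1649 treated cells.

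Lcn2, which binds bacterial siderophores, was 66.5-fold higher, AA467197 30.2-fold and Wfdc21 at least 29.3-fold. The formyl peptide receptor gene Fpr1 rose with a ratio of 109 (19.5 to 4321), and P2ry13 was at least 12.1-fold higher. L1cam (31.7-fold), Tppp3 (29.4-fold), Rfx2 (27.2-fold) and Cd177 (21.8-fold) were lower. Of 12 type I interferon genes 11 rose, such as Isg15 (4.98-fold) and Bst2 (4.68-fold) (adjusted p = 3.57e-04, adjusted p = 0.0811 with an estimated correlation). Of 15 glycolysis genes 12 rose, 13 adjusted over the list alone, with Tpi1 6.06-fold and Ldha 3.50-fold higher (adjusted p = 3.38e-05, adjusted p = 0.0811 with an estimated correlation). Of 14 MHC class I genes 11 rose and 1 fell, such as Tap2 (2.94-fold) (adjusted p = 0.00169, adjusted p = 0.0811 with an estimated correlation). Scavenging and iron handling genes had 8 of 11 up and 1 down, with Fth1, the ferritin heavy chain, 6.40-fold and Hmox1 7.79-fold higher (adjusted p = 0.0624 for Hmox1 within pools 1 and 2) (adjusted p = 0.0164, adjusted p = 0.345 with an estimated correlation). Neutrophil activation genes had 11 of 18 up and 4 down, such as Acod1 (15.3-fold) and Il1rn (5.87-fold) (adjusted p = 0.0288, 0.0538 with the pool as a block, adjusted p = 0.516 with an estimated correlation). Acod1 in treated monocyte-like cells stood at 12.7% of its level in neutrophil-like cells, without TMM factors. Whether neutrophil transcripts raised this list was not tested.

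Dissociation stress genes fell in monocyte-like cells too, 11 of 18 with 1 up, among them Fosb (7.69-fold lower) and Atf3 (5.81-fold) (adjusted p = 0.00239, adjusted p = 0.283 with an estimated correlation). Cd274 rose 2.44-fold, whereas Tnf (adjusted p = 0.0796), Cd40 (adjusted p = 0.348) and Cxcl9 (adjusted p = 0.478) were not called. Within pools 3 and 4 Tnf (0.88 on the log2 scale, adjusted p = 0.00279) and Cd40 (1.64, adjusted p = 0.0121) were called, as was Tnf in clusters made without the changed genes (1.27, adjusted p = 0.00854). Cxcl9 moved by -1.05 on the log2 scale within pools 1 and 2 (adjusted p = 9.74e-04) and by 0.85 within pools 3 and 4 (adjusted p = 0.00649). Untreated cells lay in clusters 21, 18 and 2 (236, 136 and 45 cells) and treated cells in clusters 2 and 18 (1479 and 170), and 607 genes changed in clusters made without the changed genes.

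NK-like cells after aCD40 had more Prf1, Gzmb and Mki67 transcripts. Perforin (Prf1) was 3.11-fold higher (1155 ± 331 to 3554 ± 399.6 CPM, n = 4 pools, adjusted p = 1.57e-06) and granzyme B (Gzmb) 1.90-fold higher (5379.9 ± 1644 to 10237 ± 581 CPM, adjusted p = 3.99e-04, and 0.156 within pools 1 and 2). Mki67, a gene of cycling cells, rose with a ratio of 10.2 (3.45 to 50.0). Ifng averaged 472 ± 208 CPM before and 2123 ± 1457 CPM after treatment, and was not called over the 4 pools (adjusted p = 0.0708). Within pools 1 and 2 it rose by 1.43 on the log2 scale (adjusted p = 4.17e-04) and within pools 3 and 4 by 2.53 (adjusted p = 2.04e-27). Of 1865 genes tested, 388 changed, 203 up and 185 down, in 210 untreated and 910 treated cells.

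Ly6a, an interferon-induced surface protein, rose from 1 UMI with a ratio of 207 (37.1 to 8187), and Tgm2 (at least 7.32-fold), Cdk1 (at least 7.72-fold), Marcksl1 (at least 5.64-fold) and Acod1, also a neutrophil gene (at least 5.54-fold), were higher with no UMI in untreated cells. So was Lyz2 (at least 12.9-fold, adjusted p = 0.0941 without pool 3), a gene of myeloid cells. Cd7 (20.5-fold), S100a4 (17.3-fold), Cd3g (15.8-fold), the tissue residence integrin Itga1 (11.9-fold) and the TRAIL gene Tnfsf10 (9.42-fold) were lower. Of 18 proliferation genes 16 rose, 17 adjusted over the list alone, with Pclaf 14.0-fold and Stmn1 9.09-fold higher (adjusted p = 2.46e-10, adjusted p = 0.0538 with an estimated correlation). Of 11 glycolysis genes 8 rose, such as Ldha (4.07-fold) (adjusted p = 1.77e-06, adjusted p = 0.0173 with an estimated correlation). Of 12 IFN-gamma response genes 7 rose, 8 adjusted over the list alone, such as Gbp2 (9.14-fold) and Irf8 (3.43-fold) (adjusted p = 1.46e-04, adjusted p = 0.0373 with an estimated correlation), and of 12 TNF and NF-kB genes 5, 8 adjusted over the list alone, with Nfkb2 14.1-fold higher (adjusted p = 2.05e-04, adjusted p = 0.0538 with an estimated correlation). MHC class I (6 of 15 up, adjusted p = 0.0233, adjusted p = 0.0914 with an estimated correlation) and B cell activation genes (3 of 5 up, adjusted p = 0.0204, adjusted p = 0.194 with an estimated correlation) rose as lists.

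Dissociation stress genes (7 of 13 down, 1 up, adjusted p = 0.00207, adjusted p = 0.194 with an estimated correlation) and mitochondrially encoded genes (4 of 11 down, adjusted p = 0.00751, adjusted p = 0.194 with an estimated correlation) fell in NK-like cells. Neither was called with each set of pools summed (adjusted p = 0.0992 for both). The cytotoxic effector list as a whole was not called (5 of 17 up, 2 down, adjusted p = 0.0871). Untreated NK-like cells came from clusters 11.1 and 6 (112 and 98 cells) and treated ones from cluster 6 (906 of 910), so Itga1, Cd3g and Cd7 also separate the clusters. Prf1 was among the top 10 genes of cluster 6 but not of cluster 11.1. Whether its rise follows the mix of clusters was not tested.

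T-like cells after aCD40 carried an interferon program and more granzyme. Gzmb was 4.53-fold higher (657 ± 174 to 2981 ± 378 CPM, n = 4 pools, adjusted p = 1.93e-08) and Ly6a 7.46-fold. Ifng rose 1.77-fold (adjusted p = 0.0289) and Mki67 2.05-fold (adjusted p = 0.028), while Prf1 was not called (adjusted p = 0.158). It was called in clusters made without the changed genes (0.94 on the log2 scale, adjusted p = 0.00652). The call for Ifng was lost within pools 1 and 2 (adjusted p = 0.286) and without pool 2, 3 or 4 (adjusted p of 0.0647, 0.0848 and 0.0952) and that for Mki67 without pool 1, 3 or 4 (adjusted p of 0.163, 0.0539 and 0.0667). Of 2736 genes tested, 607 changed, 311 up and 296 down, in 869 untreated and 1008 treated cells. Cxcl10 (39.0-fold), Tgm2 (by 4.32 on the log2 scale), the immunity-related GTPase Iigp1 (17.9-fold), Gbp2 (11.8-fold), Gadd45g (8.57-fold), Clic4 (7.81-fold) and the myeloid gene Lyz2 (11.8-fold, adjusted p = 0.652 in clusters made without the changed genes) rose, as did AA467197 (ratio 53.1 (17.9 to 259)). Mmp9 (6.99-fold, adjusted p = 0.405 in those clusters and not called within pools 1 and 2 at -1.13 on the log2 scale), Rflnb (5.93-fold), Sesn1 (5.37-fold), Mxd4 (4.35-fold), Itga1 (4.28-fold, adjusted p = 0.208 within pools 1 and 2) and Itga4 (4.08-fold) fell.

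Of 18 IFN-gamma response genes 17 rose in T-like cells, such as Igtp (5.07-fold) (adjusted p = 3.85e-16, adjusted p = 0.0284 with an estimated correlation), and of 11 type I interferon genes 11, such as Isg15 (6.32-fold) and Usp18 (4.87-fold) (adjusted p = 6.88e-11, adjusted p = 0.0284 with an estimated correlation). Of 19 proliferation genes 15 rose, 19 adjusted over the list alone, with Top2a 3.61-fold and Pclaf 3.65-fold higher (adjusted p = 4.18e-11, adjusted p = 0.0634 with an estimated correlation). MHC class I genes had 14 of 17 up, such as Tapbp (2.52-fold) (adjusted p = 1.87e-10), glycolysis genes 9 of 11, such as Aldoa (2.79-fold) (adjusted p = 2.15e-08), and TNF and NF-kB genes 9 of 13, such as Bcl3 (4.74-fold) (adjusted p = 1.61e-07). These 3 lists kept adjusted p of 0.0284, 0.0284 and 0.0338 with an estimated correlation. Cytotoxic effectors had 7 of 13 up and 1 down, with Gzma 4.02-fold and the interleukin-2 receptor gene Il2ra 3.50-fold higher and Klrk1 2.58-fold lower (adjusted p = 0.0112, adjusted p = 0.0634 with an estimated correlation). Mitochondrially encoded genes fell, 12 of 13, such as mt-Nd2 (1.70-fold) (adjusted p = 4.02e-06, adjusted p = 0.127 with an estimated correlation), as did 11 of 16 translation genes, 13 adjusted over the list alone, such as Rps18 (1.75-fold) (adjusted p = 3.81e-05, adjusted p = 0.164 with an estimated correlation). T-like cells lay in clusters 10, 11.0, 11.2, 16, 22 and 23, of which cluster 11.0 held 312 of 869 untreated and 31 of 1008 treated cells.

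B-like cells after aCD40 had more Pclaf transcripts and fewer of H2-Ab1 and H2-Ob. Pclaf, a DNA replication factor, was 45.2-fold higher (12.7 ± 12.1 to 635 ± 75.8 CPM, n = 4 pools, adjusted p = 1.74e-13). H2-Ab1 was 2.79-fold lower (2889 ± 211 to 1030.0 ± 54.2 CPM, adjusted p = 4.24e-10) and H2-Ob, a class II peptide loading regulator, 7.45-fold lower (816 ± 94.7 to 106 ± 20.6 CPM, adjusted p = 6.37e-13). Cd40 rose 2.56-fold (87.3 ± 11.8 to 227 ± 8.04 CPM, adjusted p = 9.52e-07). Of 4125 genes tested, 2468 changed, 1228 up and 1240 down, in 1749 untreated and 900 treated cells.

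Of 23 proliferation genes 22 rose in B-like cells, among them Tpx2 (28.4-fold) and Ube2c (ratio 54.0 (14.6 to 451)) (adjusted p = 7.72e-14, adjusted p = 0.0856 with an estimated correlation). The replication genes Uhrf1, Mybl2, Hells and Melk rose with ratios of 54.9 (18.5 to 269), 62.1 (10.8 to 2487), 44.1 (11.9 to 369) and 46.8 (8.03 to 1883), and Mcm10 by 5.17 on the log2 scale. Ccl22 was at least 44.1-fold higher (adjusted p = 0.132 without pool 1 and 0.316 within pools 3 and 4). Cd55 (32.4-fold), Pgap1 (21.1-fold), Plk2 (18.3-fold), Tcp11l2 (18.2-fold) and S1pr1, which guides exit from tissue (17.4-fold), were lower. Of 11 MHC class II genes 10 fell, 11 adjusted over the list alone, with H2-Oa 3.47-fold lower (adjusted p = 8.06e-05, adjusted p = 0.0505 with an estimated correlation), while of 16 MHC class I genes 11 rose and 1 fell, such as Psmb9 (3.69-fold) and H2-K1 (2.17-fold) (adjusted p = 0.00245, adjusted p = 0.0856 with an estimated correlation). The change of H2-Ab1 differed between B-like and Kupffer-like cells by 2.71 on the log2 scale in a fit with a class by treatment term (adjusted p = 2.34e-16).

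Glycolysis genes rose in B-like cells, 9 of 12 and 10 adjusted over the list alone, with Hk2 12.4-fold and Ldha 5.34-fold higher (adjusted p = 5.42e-05, adjusted p = 0.0856 with an estimated correlation). IFN-gamma response genes had 11 of 15 up and 1 down, such as Gbp2 (12.7-fold) and Irgm1 (4.68-fold) (adjusted p = 0.00245, adjusted p = 0.132 with an estimated correlation), and type I interferon genes 4 of 6 up and 1 down, such as Isg15 (higher by 4.46 on the log2 scale) (adjusted p = 0.0112, adjusted p = 0.0856 with an estimated correlation). Dissociation stress genes had 12 of 16 down and 2 up, such as Fos (6.88-fold lower) and Junb (4.05-fold) (adjusted p = 0.0057, adjusted p = 0.454 with an estimated correlation). Mitochondrially encoded genes had 12 of 13 down, such as mt-Co1 (2.04-fold) (adjusted p = 0.00349, adjusted p = 0.241 with an estimated correlation). The neutrophil marker S100a8 was higher by 4.90 on the log2 scale in B-like cells (7.61 to 191 CPM, adjusted p = 0.0122, adjusted p = 0.0742 without pool 2 and 0.220 within pools 3 and 4). Untreated B-like cells lay in clusters 7 and 8 (906 and 824 of 1749) and treated ones in cluster 9 (788 of 900).

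DC-like cells after aCD40 had more Fscn1, Ccr7 and Cd40 transcripts. Fscn1 was 32.7-fold higher (264 ± 93.4 to 8646 ± 1891 CPM, n = 4 pools, adjusted p = 5.28e-17), Ccr7 9.42-fold (248 ± 100.4 to 2404 ± 294 CPM, adjusted p = 6.19e-12) and Cd40 18.3-fold (69.7 ± 14.6 to 1291 ± 287 CPM, adjusted p = 1.45e-12). The T cell attractant Ccl22 was 29.0-fold higher and the costimulatory gene Cd86 6.46-fold. Of 1530 genes tested, 631 changed, 310 up and 321 down, in 384 untreated and 227 treated cells. Most untreated cells lay in cluster 14 (369 of 384) and most treated ones in clusters 15.1 and 15.2 (126 and 81 of 227), so these genes also separate the clusters, and 328 genes changed in clusters made without the changed genes.

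The semaphorin gene Sema7a (45.3-fold), Serpinb9 (22.1-fold), Apol7c (20.5-fold) and Acod1 (17.8-fold) rose in DC-like cells, as did Procr (ratio 53.3 (17.7 to 263)) and Cd200 (ratio 33.0 (8.61 to 282)). Id3 (25.3-fold) and Cd244a (at least 11.9-fold) were lower, and Cd209a, a marker of one dendritic cell subset, fell to a ratio of 0.0240 (0.00288 to 0.0885). Of 15 MHC class I genes 14 rose, with B2m 3.38-fold and H2-K1 3.48-fold higher (adjusted p = 5.47e-07, adjusted p = 0.0408 with an estimated correlation). A further 5 lists rose: IL-12 family and costimulation (5 of 6 genes up, among them Ebi3, 7.53-fold, adjusted p = 4.17e-06), B cell activation (6 of 7 up, adjusted p = 1.95e-05), TNF and NF-kB (12 of 20 up and 1 down, among them Relb, 5.73-fold, adjusted p = 1.97e-04), IFN-gamma response (8 of 12 up, among them Irf1, 2.81-fold, adjusted p = 0.00214) and type I interferon (4 of 7 up, among them Oasl2, 4.47-fold, adjusted p = 0.0038). With an estimated correlation the first 3 had adjusted p of 0.0243, 0.0243 and 0.0302 and the last 2 adjusted p = 0.141. Neutrophil activation genes (7 of 13 up, 2 down) also rose, such as Fpr2 (12.4-fold) and Clec4e (11.7-fold) (adjusted p = 0.0156, adjusted p = 0.141 with an estimated correlation). Clec4e also marked cluster 15.2, beside the myeloid genes Clec5a, Csf1r and Tlr2, and Acod1 in treated DC-like cells stood at 4.31% of its level in neutrophil-like cells, without TMM factors. Translation genes fell, 12 of 16 and 15 adjusted over the list alone, such as Rps3 (2.14-fold) (adjusted p = 1.75e-04, adjusted p = 0.141 with an estimated correlation), as did 10 of 17 dissociation stress genes, such as Egr1 (8.97-fold) (adjusted p = 0.00113, adjusted p = 0.141 with an estimated correlation).

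EYFP+ DC-like cells of treated mice differed between tumor and liver in interferon response and MHC class II genes. The series text counts 2 EYFP+ livers and 3 tumors. The 3 liver letters thus cannot all be different animals, and p-values describe letters only. Tissue dissociation went with the tissue, so its part in the differences cannot be told apart. Cxcl9 was 27.6-fold lower in tumor (1044 ± 122 in liver to 45.4 ± 21.1 CPM in tumor, n = 3 letters each, adjusted p = 1.25e-16), H2-Ab1 8.52-fold lower (1769.9 ± 114 to 214 ± 33.4 CPM, adjusted p = 1.95e-16) and its activator Ciita 24.3-fold lower. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, was 11.6-fold higher in tumor (52.5 ± 14.5 to 573 ± 54.4 CPM, adjusted p = 2.91e-16), and Ccr7 1.53-fold higher (adjusted p = 1.38e-05). Of 6012 genes tested, 1494 differed, 704 higher and 790 lower in tumor, between 4121 liver and 1641 tumor cells.

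The growth factor gene Areg (14.8-fold), Sphk1 (15.8-fold), Ceacam15 (10.9-fold), Ceacam1 (10.8-fold), Cdh26 (10.2-fold), Gapt (10.1-fold), Dab2 (8.95-fold), Ears2 (8.93-fold) and the decoy receptor gene Il1r2 (8.69-fold) were higher in tumor. Ubd, with 357 UMIs in liver, had none in tumor (at least 40.1-fold lower), nor had Serping1 (at least 19.0-fold), Kcna2 (at least 12.9-fold) or the immunoglobulin gene Ighm (at least 16.3-fold). Ly6i and Hk3 had 1 tumor UMI each and tumor to liver ratios of 0.00388 (9.80e-05 to 0.0217) and 0.0127 (3.21e-04 to 0.0717). Tnf was 9.76-fold lower in tumor and Cd40 1.59-fold lower, and Cd274 1.37-fold higher (adjusted p = 0.429 without letter I, 0.166 without letter J and 0.109 with the letter as a block). Of 11 MHC class II genes 10 were lower and none higher, such as H2-DMb2 (7.50-fold) (adjusted p = 1.53e-09, adjusted p = 0.0192 with an estimated correlation). Of 17 MHC class I genes 3 were lower and 2 higher (adjusted p = 0.999). IFN-gamma response genes had 17 of 24 lower and 2 higher, 18 and 2 adjusted over the list alone (adjusted p = 1.08e-08, adjusted p = 0.0192 with an estimated correlation), and type I interferon genes 10 of 13 lower, 12 adjusted over the list alone, such as Zbp1 (5.30-fold) and Irf7 (4.22-fold) (adjusted p = 4.96e-07, adjusted p = 0.0242 with an estimated correlation). Neutrophil activation genes had 9 of 16 lower and 4 higher, such as Acod1 (31.9-fold lower) (adjusted p = 0.048, 0.0584 with the letter as a block, adjusted p = 0.461 with an estimated correlation). Clusters 3 and 8, with 709 and 363 liver and 7 and 11 tumor cells, carried neutrophil and monocyte transcripts, S100a8, S100a9 and Lyz2 in cluster 3 and Clec4e and Lyz2 in cluster 8. Whether those cells set the levels of Tnf, Acod1 and the neutrophil activation list in liver was not tested. Tumor cells lay mainly in clusters 0, 5 and 6 and liver cells in clusters 1, 2, 3 and 4, and the DC-like class without the changed genes had 1641 genes called.

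**Figure D4:**
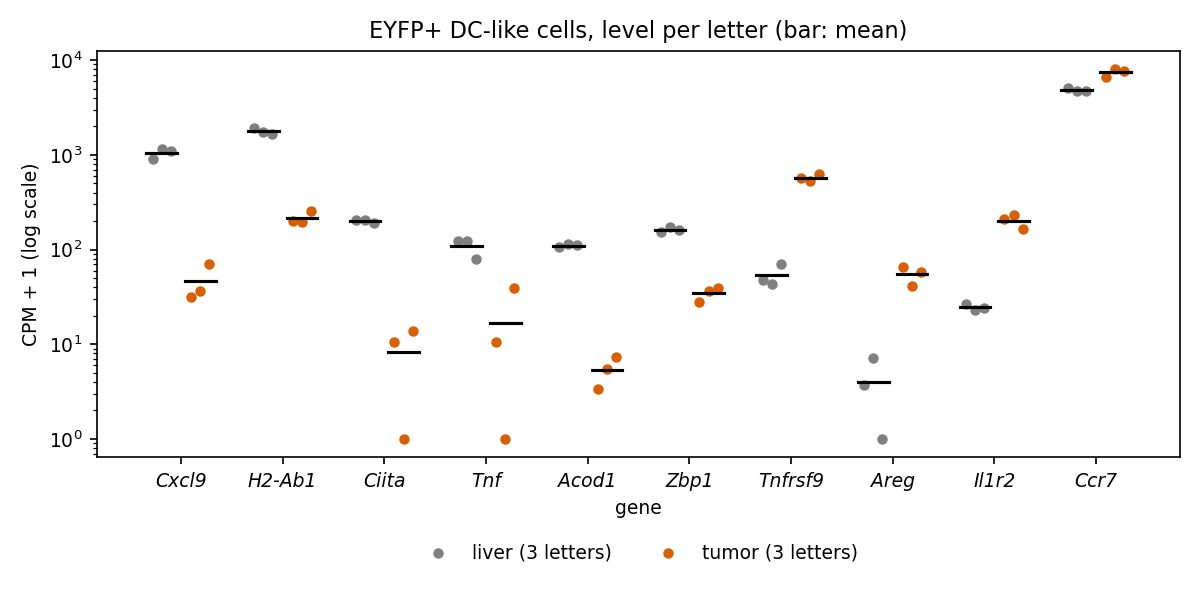
Level in CPM plus 1 (y axis, log scale) of 10 genes (x axis) in EYFP+ DC-like cells from liver and from tumor of aCD40-treated mice; points are the 3 letters per tissue and bars mark means. Cxcl9, H2-Ab1, Ciita, Tnf, Acod1 and Zbp1 were lower and Tnfrsf9, Areg, Il1r2 and Ccr7 higher in tumor in every letter than in every liver letter.

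Among all EYFP+ cells, DC-like cells were 84.6 ± 1.39% in liver and 99.5 ± 0.190% in tumor (SD, n = 3 letters per tissue, adjusted p = 2.20e-04, 0.0779 without letter I and 0.945 with TMM factors). Cluster 7, which carried Kupffer cell markers beside those of mature dendritic cells, was 9.37 ± 2.00% of liver and 0.0403 ± 0.0698% of tumor cells, and clusters 10 and 12, left unnamed, were 5.28 ± 0.866% and 0.431 ± 0.199%. The exact permutation test of 3 against 3 cannot go below 0.1, the value it gave for these classes. In clusters made without the changed genes, DC-like cells were 97.2 ± 0.118% and 99.8 ± 0.225%, and the change was not called (0.0384 on the log2 scale, adjusted p = 0.353). The tissues lay apart there, and a test on cell counts has little power for a class that holds nearly all cells. Endothelial-like cells, at 1.34 ± 0.153% and 0.186 ± 0.225%, were called (adjusted p = 0.00546). The EYFP gate selects reporter-bright cells, so these shares describe the gated cells only.

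Il12b itself was rarely sampled. In EYFP+ DC-like cells, 2.40% of 4121 liver cells (104 UMIs, median depth 805 UMIs) and 1.04% of 1641 tumor cells (17 UMIs, median depth 590) had an Il12b UMI. Letters I, J and K gave 16, 0 and 1 of the tumor UMIs, so the tumor value rests on letter I. In cells thinned to 500 UMIs, which leaves out 1031 liver and 627 tumor cells of lower depth, the shares were 1.17% (95% Clopper-Pearson interval 0.817 to 1.61%) and 0.493% (0.160 to 1.15%), and in summed counts Il12b was not called (-1.07 ± 0.42 on the log2 scale, tumor against liver, adjusted p = 0.0626, and 0.0367 with the letter as a block and 0.0111 in clusters made without the changed genes). In EYFP+ liver cells, cluster 10 held 23 Il12b UMIs in 223 cells (8.07% of cells). Treated T-like cells, which should lack the gene, had none in 1008 CD45+ cells at a median depth of 819 UMIs. They came from other pools than the EYFP+ cells, so they do not measure free RNA in pool 5. Among CD45+ cells, untreated ones had no Il12b UMI and treated ones 4. Of these, 2 were in the 12 cells of cluster 15.3 (8.33% of its cells), 1 in 467 inflammatory macrophage-like cells and 1 in 227 DC-like cells. Kupffer-like, neutrophil-like, monocyte-like, NK-like, T-like and B-like cells had none. Cluster 15.3, a part left unnamed, had mature dendritic cell genes such as Ccl22, Fscn1 and Ccr7 among its top genes. Neutrophil genes such as S100a9 set it apart from the rest of cluster 15.

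The eYFP sequence held more UMIs than Il12b. EYFP is made from the Il12b transcript in these mice, so UMIs of that transcript may be counted under either name. Few Il12b UMIs in a class therefore do not show that the class lacks the transcript. In CD45+ DC-like cells eYFP rose from 79.6 ± 95.1 to 597 ± 499 CPM (here and below without TMM factors) after aCD40 (exact two-sided permutation p = 0.0286, n = 4 pools). Treated pools 1 to 4 held 249, 229, 1297 and 611 CPM and untreated ones 29.5, 215, 74.1 and 0 CPM, so the size of the rise rests on pools 3 and 4. Of the treated DC-like cells, 34 of 227 at a median depth of 867 UMIs had an eYFP UMI, against none of 1008 treated T-like cells. In Kupffer-like cells it averaged 4.69 ± 6.35 and 665 ± 641 CPM (exact permutation p = 0.143). EYFP+ DC-like cells held 3294 ± 283 CPM in liver and 3209 ± 349 CPM in tumor, cluster 7 held 7167 ± 872 CPM and cluster 10 held 11737 ± 1171 CPM in liver. Neutrophil-like cells had 8 eYFP UMIs in 6481 treated cells and none in untreated cells.

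On GRCm38, Il12b lies on chromosome 11 from 44400063 to 44414033, Clec4f on chromosome 6 from 83644542 to 83656187, Cxcl9 on chromosome 5 from 92321347 to 92328079, Tnf on chromosome 17 from 35199381 to 35202007, and H2-Ab1 on chromosome 17 from 34257689 to 34269419. Fscn1 lies on chromosome 5 from 142960343 to 142973185, Gzmb on chromosome 14 from 56258838 to 56262260, Ifng on chromosome 10 from 118441046 to 118445892, Ccr7 on chromosome 11 from 99144196 to 99155077, and Ubd on chromosome 17 from 37193892 to 37196095.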

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

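Of the tests in this part, those of dilution, of lost markers, of free RNA as the main source, of neutrophils placed in lymphoid classes and of mature dendritic cells mixed into a class were chosen only after the result was seen.

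Kupffer-like cells fell as a share of CD45+ liver cells after aCD40. Dilution by infiltrating cells alone would leave their ratio to B-like plus T-like cells as it was, and that ratio changed by -2.45 on the log2 scale (SE 0.102), which argues against it as the whole cause. Kupffer cells that lost their marker genes may have been counted in another macrophage class: the ratio of Kupffer-like, monocyte-like and inflammatory macrophage-like cells together changed by 0.89 (SE 0.226). As monocyte-like cells alone changed by 2.42, arriving monocytes can hide such a shift, and this stays open. Death of Kupffer cells and a lower yield from treated tissue were not tested.

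Neutrophil transcripts appeared in treated B-like, T-like and NK-like cells. The 5% of these 2818 cells with the most neutrophil marker UMIs held 84.6% of the 3170 such UMIs, against 20.5% on average and at most 21.6% in 200 draws from each cell's depth, which argues against free RNA as the main source. Markers of the cells' own class were at 0.876 of the level in the other cells, which argues against neutrophils placed in these classes. Doublets of a neutrophil and a lymphocyte stay open: 84.6% in few cells is what they would give, but neutrophil markers there reached 10.7% of their share in neutrophil-like cells, where a doublet of equal parts would lie much higher. Free RNA as a source of the remaining 15.4% stays open (SD of up to 0.842 on the log2 scale in the ratio of 4 markers to their level in neutrophil-like cells), and no biological explanation was tested.

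Treated Kupffer-like cells carried transcripts of mature dendritic cells such as Fscn1. Free RNA is argued against by the Fscn1 level in treated T-like cells, 0.545% of that in Kupffer-like cells. Mature dendritic cells mixed into the class may supply part of it, as Fscn1 in cells with at least 3 Kupffer marker UMIs was 0.457 of that in cells with fewer (2021 against 4426 CPM, without TMM factors), and this stays open. Doublets stay open too, since cells with both sets of markers (70 cells) had 1.66 times the median UMIs of cells with 1 set (74 cells), and draws from depth alone gave 1.55 to 2.11. A change of the Kupffer cells themselves was not tested apart from these.

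A sample far from the others was found in 2 of 63 groups of 4 pools, where chance gives about 1 in 20 groups. Cxcl9 in untreated Kupffer-like cells stood at 126.8 CPM in 1 pool and at 35.5, 45.2 and 49.9 CPM in the others, a gap of 0.842 of the range. Tnf in untreated neutrophil-like cells stood at 132.6 CPM in 1 pool and at 365.6, 370.9 and 371.2 CPM in the others, a gap of 0.977 of the range.

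Changes of MHC class II genes differed between Kupffer-like and B-like cells in a fit with a class by treatment term, which found 913 of 4018 genes to differ. Of 11 class II genes 9 did, and Ctss (adjusted p = 0.351) and H2-DMa (0.273) did not. The change in Kupffer-like minus that in B-like cells on the log2 scale was 3.10 for Ciita, 6.16 for H2-Oa, 4.38 for H2-DMb2, 1.28 for H2-DMb1, 4.91 for H2-Ob, 2.71 for H2-Ab1, 1.91 for H2-Aa, 1.91 for H2-Eb1 and 1.65 for Cd74, with adjusted p from 2.34e-16 for H2-Ab1 to 0.00463 for H2-Ob. In clusters made without the changed genes, tested in pools 3 and 4 only, the changes in Kupffer-like cells were smaller (Ciita 1.37, H2-Ab1 0.75 and H2-DMb2 1.71, the last with adjusted p = 0.0618). Clusters and pools changed together there, so their parts cannot be told apart. Mature dendritic cells or doublets in that class stay open as a source.

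Ifng was found in cells that belong to no comparison: part of cluster 20, which mixed NK cell and T cell markers, held 570 Ifng UMIs in 267 cells, all of them treated.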

How the results depend on the processing

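Chosen only after the data were seen were the tests with no cell filter, with clusters made without the changed genes, by sets of pools, with the set as a term, and in Kupffer-like cells with marker UMIs. Over 22 main results and their alternatives, 271 of 304 values stayed the same, 22 were weaker, 8 stronger and 3 reversed. A tested value stayed the same if it kept its side of the threshold and, where called in either setting, its direction. A count did if within 1.5 times, and an Il12b share if inside the main interval. Over 260 single genes and small classes, 4095 of 4204 stayed the same, 69 were weaker, 34 stronger and 6 reversed. Except where said, the cause was not tested. Without the low-count filter, which adds genes to the test, 1282 genes were called in Kupffer-like (733 with it), 1710 in monocyte-like (1061) and 732 in NK-like cells (388), there 610 up and 122 down against 203 and 185. In random draws of 2 units of 4 libraries, which mix the sets of pools, the median was 1211.5 in Kupffer-like, 2184 in monocyte-like, 663.5 in NK-like, 996 in T-like (607) and 1062 in DC-like cells (631). With 2 summed sets of pools per group 224 genes were called in NK-like and 293 in T-like cells (208 up and 85 down against 311 and 296), and in pools 1 and 2 alone 349 in DC-like cells. Cells of at least 600 UMIs gave 162 in NK-like cells, and clusters made without the changed genes 607 in monocyte-like and 328 in DC-like cells. DESeq2 gave 404 in T-like cells (250 up, 154 down) and 822 between tumor and liver (1494), where libraries as units gave 931 and leaving out a letter 902 (without J) to 1596 (without K). In Kupffer-like cells the split into up and down, 353 and 380, became 323 and 525 with DESeq2, 291 and 469 with RLE, and 294 and 988 without the low-count filter. Over the genes followed through the alternatives (97 to 230 per test), scaling moved the median by -0.17 (RLE) and -0.28 (DESeq2) in Kupffer-like cells, and with DESeq2 by 0.14 in neutrophil-like, 0.19 in NK-like, -0.12 in DC-like and -0.14 in pDC-like cells.

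On the log2 scale the share of DC-like cells (-2.03) was 3.25 at a resolution of 0.8, and that of monocyte-like cells (0.73) was -3.32 there, -0.41 with at least 600 UMIs, 0.20 with no cell filter, 0.28 in clusters made without the changed genes and 0.74 with summed sets of pools (adjusted p = 0.0550). The share of inflammatory macrophage-like cells (5.64) was -5.68 with at least 600 UMIs and -5.53 with no cell filter, and that of unnamed cells -1.62 with doublet calls kept and -2.78 in clusters made without the changed genes. Its main value is a fitted 8.65, as no untreated cell was unnamed, so its size is not known. The share of T-like cells (-0.98) was -0.22 with TMM. Among EYFP+ classes, of which 4 differed, 2 did with no cell filter and in clusters made without the changed genes, and 2 (without I) to 5 (without K) when a letter was left out. With TMM, DC-like (adjusted p = 0.945) and endothelial-like cells (adjusted p = 0.0820) were not called. The share of EYFP+ DC-like cells (0.23) was 0.30 with at least 600 UMIs, 0.26 with no cell filter and 0.00306 with TMM. It was 0.0384 in clusters made without the changed genes and 0.22 (without I) to 0.24 (without J) without a letter. Cxcl9 in monocyte-like cells (-0.33) was 2.00 with no cell filter and 0.85 in pools 3 and 4 only. Of 68 list tests called, an estimated correlation left 18. Il12b was in 1.17% of EYFP+ liver DC-like cells thinned to 500 UMIs (3090 of 4121 cells), and in 1.07% thinned to 300, with overlapping intervals (0.817 to 1.61% and 0.777 to 1.43%).

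With the pool or letter as a block, 734 genes were called in Kupffer-like, 1504 in neutrophil-like, 1233 in monocyte-like, 488 in NK-like, 754 in T-like, 2581 in B-like and 611 in DC-like cells, and 1146 between tumor and liver. Shares then changed by -4.13 (Kupffer-like), 3.16 (neutrophil-like), 0.73 (monocyte-like), 1.05 (NK-like), -0.98 (T-like), -2.21 (B-like) and -1.998 (DC-like), EYFP+ DC-like cells by 0.23, and 65 list tests were called. The set of pools as a term gave 781, 1649, 1365, 544, 823, 2651 and 645 genes in Kupffer-like, neutrophil-like, monocyte-like, NK-like, T-like, B-like and DC-like cells. With the pool block and with the set term 3 more genes were called: Ifng in NK-like (2.04 and 2.08 on the log2 scale), Tnf in monocyte-like (0.57 and 0.58) and S100a8 in neutrophil-like cells (0.29 and 0.29). With the set term Ccl22 in B-like (adjusted p = 0.0971) and Lyz2 in NK-like cells (adjusted p = 0.272) were lost. Leaving out 1 pool gave 602 to 736, 1133 to 1342, 831 to 901, 263 to 345, 423 to 531, 1999 to 2589 and 448 to 634 genes in Kupffer-like, neutrophil-like, monocyte-like, NK-like, T-like, B-like and DC-like cells. The planned test of EYFP+ monocyte or macrophage-like cells, and so its alternatives, could not be run for want of cells in both tissues, and an alternative in which a class lacked cells or a name gave no value.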

Other observations

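The test of pDC-like cells, the counts of UMIs by class, the comparison of libraries and the counts over other splits were chosen only after the results were seen. pDC-like cells after aCD40 carried interferon-induced transcripts. Of 776 genes tested, 91 changed, 54 up and 37 down, over 4 untreated and 3 treated pools (199 and 120 cells). The GTPase gene Iigp1 rose with a ratio of 81.7 (14.1 to 3283), and the cell cycle inhibitor Cdkn1a was 11.3-fold higher, Isg15 9.71-fold, Ly6a 4.60-fold and H2-Q7 3.98-fold. Cd209d and Ccr2 fell to ratios of 0.0186 (4.65e-04 to 0.107) and 0.0717 (0.00839 to 0.276) (adjusted p = 0.0940 for Ccr2 without pool 4). Of 13 MHC class I genes 9 rose (adjusted p = 1.25e-08, adjusted p = 0.0242 with an estimated correlation), and of 7 IFN-gamma response genes 4 rose (adjusted p = 0.00287, adjusted p = 0.13 with an estimated correlation). Dissociation stress genes had 3 of 12 down (adjusted p = 0.00287, adjusted p = 0.253 with an estimated correlation). The count of 91 was 58 without pool 1, 84 without pool 2, 39 without pool 3 and 29 without pool 4, and 30 with DESeq2.

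The class with most Ifng, Tnf or Cxcl9 UMIs, a sum that follows the number of its cells, differed between untreated and treated CD45+ cells. For Il15 it was neutrophil-like cells in both (52.3% of 109 and 86.4% of 951 UMIs). Of 2687 Ifng UMIs in treated cells, 66.1% were in NK-like cells, 21.2% in part of cluster 20 and 11.3% in T-like cells, whereas of 167 in untreated cells 67.1% were in T-like and 30.5% in NK-like cells. Of 23867 Tnf UMIs in treated cells 91.7% were in neutrophil-like cells, and of 301 in untreated cells 37.9% were in monocyte-like and 30.6% in neutrophil-like cells. Cxcl9 had 5792 UMIs in treated cells, 39.9% in neutrophil-like, 25.8% in inflammatory macrophage-like, 13.8% in monocyte-like and 10.4% in Kupffer-like cells, and 362 in untreated cells, 53.6% in monocyte-like and 34.0% in DC-like cells. Nos2 had 2128 UMIs in treated cells, 47.4% in inflammatory macrophage-like, 37.7% in neutrophil-like and 11.7% in monocyte-like cells, and 1 in untreated cells. These are sums over all pools and follow class size. Ifng averaged, without TMM factors, 366 CPM in NK-like and 161 CPM in T-like untreated cells, and 1660 and 294 CPM in treated ones. Tnf averaged 337 CPM in neutrophil-like and 282 CPM in monocyte-like untreated cells, and 2979 and 410 CPM in treated ones. Cxcl9 averaged 456 CPM in untreated monocyte-like cells. In treated cells it averaged 5204 CPM in 149 Kupffer-like and 315 CPM in 6481 neutrophil-like cells. Pools 1 to 4 gave 9, 12, 224 and 222 of the treated inflammatory macrophage-like cells, so the parts given for that class, and its place before others, rest on pools 3 and 4.

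Libraries of pool 5 did not group by letter. By the chi-square statistic per degree of freedom, runs of 1 letter differed by a median of 4.40 in liver and 2.43 in tumor, and libraries of different letters by 2.34 and 2.09. Liver libraries of I and J grouped by run: the runs named rep1 differed by 1.23 and those named rep2 by 1.37. Pairs of a rep1 and a rep2 library differed by 4.29 to 4.73. In tumor the rep1 runs differed by 1.47 and the rep2 runs by 2.97. Sums of letters I and J in the tests hold both runs.

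In 35 splits of the 8 pool sums into 4 and 4, the split by treatment was the 1 with most genes for each class tested. Only if the sums are taken as independent does the rank of the split by treatment, 1 in 35, argue against chance as the cause of the counts. Pools 1 and 2 resembled one another, as did pools 3 and 4, and 18 splits put 2 sums of each set on each side, too few for such a statement. The real count was 733 in Kupffer-like, 1445 in neutrophil-like, 1061 in monocyte-like, 388 in NK-like, 607 in T-like, 2468 in B-like and 631 in DC-like cells, with 0 as the highest of the other splits for each. Every other split mixed treated and untreated sums, which widens the spread within a side, so these counts of 0 do not gauge false calls. For pDC-like cells, with 7 sums, the real count was 91 and the highest other 16. Between tumor and liver the 10 splits are too few for such a statement, with a real count of 1494 and 0 as the highest other.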
